A study of Danio rerio with 8 samples.

How the data were processed

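RNA from 8 zebrafish embryo samples, 4 control and 4 exposed to 7,17-diHDPAn-3, was measured by RNA sequencing. Per the labels' protocols, libraries were made from total RNA with a stranded low-input total RNA kit that removes ribosomal cDNA with probes for mammalian sequences, and were sequenced as paired 100 bp reads on an Illumina NovaSeq. The authors deposited 1 table of whole-number counts per gene for all 8 libraries. Per the submitters' processing notes, CASAVA 1.8.2, Trim Galore 0.5.0, HISAT2 2.1.0, StringTie 1.3.3b and DESeq2 1.22.1 and the genome build GRCz11 were used, and the notes as used here give no role or order. The annotation release, the strand setting of the counting and how the counts were made are not given in the sources used here. Counts of overlapping, antisense or near-identical genes are therefore uncertain. Totals were 2502636 to 4794081 counts per library, and reads made by PCR are not independent molecules. The interval given below for the red cell score rests on the spread between libraries.

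The table holds 32020 rows with Ensembl gene IDs, 28975 of which matched a symbol in the name table supplied with the data. Many symbols are written in the human style, and 1770 names belong to 2 or more rows. Rows without a name held 24.6% ± 0.760 of counts in controls and 24.9% ± 1.18 in treated libraries (SD, n = 4) and stayed in the main test. No row carried a mitochondrial gene name, so the mitochondrial share and list were not computed. No coordinates are given because no annotation of the build was used here. 0 sample columns were left out.

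Groups came from the treatment labels. Counts were scaled by TMM and filtered with filterByExpr in edgeR 4.0.16 (R 4.3.3), which left 14249 genes. Treated and control libraries were compared with edgeR's quasi-likelihood F-test with robust dispersion and no covariate, at a Benjamini-Hochberg adjusted p of at most 0.05. Fold changes are treated over control. The biological coefficient of variation was 0.265. Log2 CPM values for scores and principal components used a prior count of 2.

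34 gene lists fitting red cells, blood, inflammation, lipid mediators, stress, metabolism and other cell types of the embryo were written before the data were examined: embryonic and adult globins, heme synthesis, iron handling, red cell structure and enzymes, erythroid regulators, red cell maturation and autophagy, hematopoietic stem and progenitor, thrombocyte, myeloid, inflammatory signalling, interferon response, lipid mediators, DNA replication, mitosis, mitochondrial and nuclear oxidative phosphorylation genes, cholesterol synthesis, fatty acid and PPAR, oxidative stress, unfolded protein response, heat shock, p53 and apoptosis, hypoxia and glycolysis, endothelial, muscle, cardiac, neural, epidermis, yolk and liver, mesenchyme with notochord and cartilage, lens, pigment cell and cytosolic ribosomal protein genes. Of 1084 list entries, 786 matched a row by symbol, 196 matched after removal of a paralog suffix and 102 matched none. 32 lists had at least 3 tested members. The adult globin list had 2 matched rows, at 2.5e-05% of counts in controls and 0% in treated libraries, and was not tested. Lists were tested with camera in limma 3.58.1 on voom values at a preset correlation of 0.01, with an estimated correlation and fry beside it. A list score is the mean over members of log2 CPM centred per gene.

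Most genes named in the text follow a rule written before the data were examined. It takes the 10 higher and 10 lower genes of largest fold change among those past the threshold with no overlap between groups, a mean of at least 5 CPM and a symbol that is not a clone or locus name. 0 genes met it, so the rule's fallback applied: the 10 genes per direction with the smallest p under the same symbol and CPM conditions, named as not passing. It further takes the 4 members of smallest p in each list past the camera threshold, up to 2 members past the threshold in other lists, and always gata1a, klf1, alas2, hbae1.1, hbbe1.1, slc4a1a, epor, runx1, myb, spi1b, il1b, tnfa and nfkb1. 2 genes that the rule takes are not reported here.

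Library measures were compared with two-sided exact permutation tests, whose smallest p for 4 against 4 libraries is 0.0286. Pairs of libraries were compared by chi-square over genes. The statistic divided by its degrees of freedom lay between 6.85 and 23.6, so no pair agreed within sampling noise. Alternatives were other scalings and filters, DESeq2 1.42.0, limma-voom with and without sample weights, 1 surrogate variable from sva 3.50.0, non-robust dispersion, removal of globin rows, and each library left out in turn. The steps were tested on simulated counts of 14249 genes with 200 of them changed. edgeR called 2 of 50 genes changed 1.5-fold, 17 of 50 changed 2-fold, 36 of 50 changed 3-fold and 42 of 50 changed 5-fold, and 3 of 14049 unchanged genes. DESeq2 called 5, 22, 39 and 43 of 50 and 10 unchanged genes. Tests and figures used Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9.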

Results

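RNA was sequenced from zebrafish embryos kept as controls or exposed to 7,17-diHDPAn-3, a dihydroxylated product of the omega-3 fatty acid docosapentaenoic acid. The labels give the tissue as embryo and the cell type as erythrocyte progenitors and erythrocytes. The sources used here do not say whether cells were sorted. Every library name contains gata_1, and that of control 4 an extra 2b, neither of which is explained. The series holds 8 libraries, 4 control (numbered 1 to 4) and 4 treated (5 to 8). Total gene counts ran from 2502636 in treated 5 to 4794081 in control 1. Controls held 4012700 ± 686200 counts and treated libraries 3343100 ± 607600 (SD, n = 4 each, two-sided exact permutation test p = 0.2, adjusted p = 0.477 over 5 library measures), a difference of -669600 that was -409100 without control 1 and -389400 without treated 5. The design text describes exposures of 1.5 µM from 11 to 36 hours post fertilization in a screen of omega-3 metabolites and a dose search from 1 to 1.75 µM. The dose and hours used for these 8 libraries are not given in the sources used here. Nothing in the labels says that the libraries of a group came from separate clutches, so p-values measure the spread between these samples, which may be technical.

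The libraries held transcripts of many embryonic tissues beside those of red cells. Rows named as globins took 1.02% ± 0.404 of all counts in controls and 0.811% ± 0.365 in treated libraries (SD, n = 4, exact permutation p = 0.286, adjusted p = 0.477). Control 1, control 3 and treated 5 held 1.36%, 1.37% and 1.34% and the other 5 libraries 0.556% to 0.748%. The difference of -0.209 percentage points was -0.095 without control 1, -0.092 without control 3, -0.346 without control 4, -0.387 without treated 5, -0.137 without treated 7 and -0.124 without treated 8. Fast and slow muscle genes took 1.68% ± 1.17 and 3.13% ± 1.03, epidermal keratin and adhesion genes 1.02% ± 0.283 and 1.02% ± 0.108, mesenchyme, notochord and cartilage genes 0.865% ± 0.155 and 0.939% ± 0.172, and neural genes 0.459% ± 0.0267 and 0.451% ± 0.0304, in control and treated libraries respectively. Muscle genes held 0.364% of the counts in control 1 and between 1.35% and 4.43% in the other 7 libraries.

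**Figure D1:**
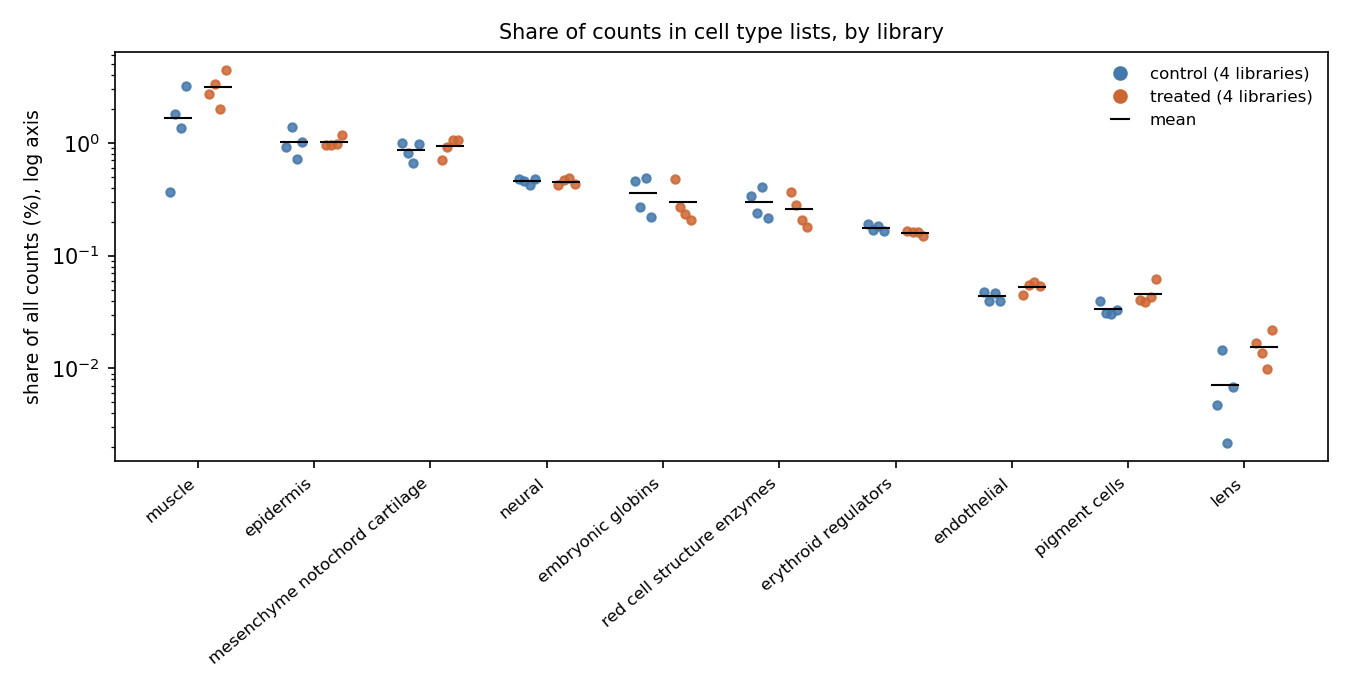
Share of all counts (percent, log axis) in the rows of 10 fixed gene lists. Each point is a library, blue for control and orange for treated, and the black line is the group mean. Muscle genes took more counts than any red cell list plotted in every library except control 1, where they held 0.364% and embryonic globins 0.459%. The embryonic globin list covers only part of the globin rows. All rows named as globins held 1.37% in control 3, where muscle genes held 1.35%.

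The comparison of treated with control libraries asked which transcripts differ after exposure to the lipid, in a series titled around hematopoietic stem cell number and erythropoiesis. The genes with the smallest p-values were atf7ip, a chromatin factor that works with the SETDB1 histone methyltransferase, and the endocytic receptors MRC1 and stab2, the latter a marker of venous and lymphatic endothelium in zebrafish. atf7ip stood at 519 ± 42.7 CPM in controls and 318 ± 36.6 CPM in treated libraries (SD, n = 4, log2 fold change -0.71 ± 0.11 SE). MRC1 stood at 4.90 ± 2.82 and 25.3 ± 8.09 CPM (2.40 ± 0.37), and stab2 at 16.1 ± 5.11 and 46.7 ± 12.6 CPM (1.55 ± 0.26). For each of these 3 genes all 4 treated libraries lay on one side of all 4 controls. None passed the threshold in edgeR's quasi-likelihood test, with adjusted p of 0.0768, 0.0768 and 0.104.

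Of 14249 genes tested, edgeR called 0 at an adjusted p of at most 0.05, and so 0 changed at least 2-fold. At an unadjusted p of at most 0.05 there were 987 genes, 517 with higher and 470 with lower treated values. Which direction held more genes was not stable: lower genes were more numerous with scaling to the total count (417 higher and 546 lower), with 1 surrogate variable (501 and 588), with no low-count filter (698 and 809), and without control 1 (503 and 505), control 3 (455 and 466), treated 5 (526 and 581), treated 6 (524 and 555), treated 7 (414 and 450) or treated 8 (397 and 450). DESeq2, run on the same counts, called 18 genes, 13 higher and 5 lower, of which 10 differed at least 2-fold, all higher. It gave 963 genes at an unadjusted p of at most 0.05. DESeq2 gave no adjusted p for 5526 of the 14249 genes, so its adjustment covered fewer genes than that of edgeR. The groups did not overlap in 659 genes, 4.62% of those tested, where chance gives 2.86%. The median standard error of a log2 fold change was 0.28. On simulated counts with the same means and library sizes, edgeR called 34% of genes changed 2-fold, 72% of those changed 3-fold and 4% of those changed 1.5-fold, so smaller changes were mostly not detectable at this depth and number of libraries.

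**Figure D2:**
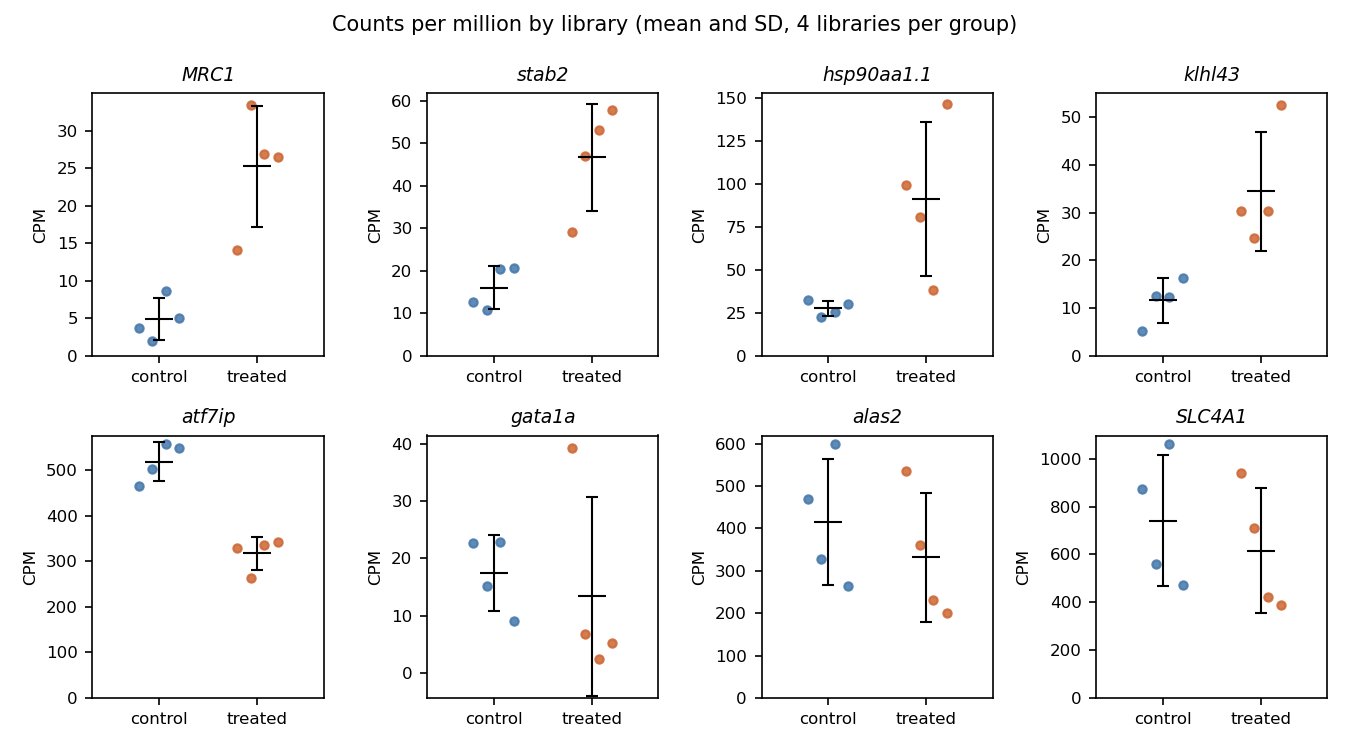
CPM (counts scaled to library size, linear axis) of 8 genes in each library, blue for control and orange for treated, with the mean and SD over 4 libraries per group in black. Treated libraries lay above all controls for MRC1, stab2, hsp90aa1.1 and klhl43 and below them for atf7ip, while gata1a, alas2 and SLC4A1 overlapped. None of the 8 passed edgeR's threshold.

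Among the DESeq2 calls, klhl43, UNC45B, a chaperone of myosin, and KLHL41, a sarcomere-associated protein, had log2 fold changes of 1.57 ± 0.35, 1.48 ± 0.33 and 1.66 ± 0.38 (SE) in DESeq2, with adjusted p of 0.00809, 0.00809 and 0.00909. In edgeR their adjusted p was 0.325 each. The inducible chaperone hsp90aa1.1, which serves myosin folding in developing muscle, stood at 27.7 ± 4.32 CPM in controls and 91.4 ± 44.8 CPM in treated libraries (adjusted p = 0.000101 in DESeq2 and 0.419 in edgeR). MRC1, atf7ip and stab2 had adjusted p of 2.13e-05, 2.73e-05 and 0.000101 in DESeq2. Among genes with lower treated values, carmil2, the nuclear export receptor XPO1 and the calcium channel subunit cacnb4b had DESeq2 log2 fold changes of -0.75, -0.62 and -0.74 with adjusted p of 0.00809, 0.00826 and 0.0494. GPM6B, a membrane glycoprotein, stood at 89.7 ± 4.76 and 129.9 ± 3.92 CPM, and FH, the fumarate hydratase of the citric acid cycle, at 20.7 ± 3.68 and 36.9 ± 1.88 CPM, with DESeq2 adjusted p of 0.00508 and 0.0303. Further genes chosen by rank, none of which passed in edgeR, were ehbp1l1b, FBLN1 and fli1rs, with log2 fold changes of 1.17, 1.31 and 1.54, and SLC1A4, FOXQ1, BRINP1, scg2b and CHMP1A, with values from -0.78 for SLC1A4 to -1.14 for FOXQ1.

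Single red cell genes were not shown to differ between the groups. gata1a, the master regulator of erythropoiesis, stood at 17.4 ± 6.66 CPM in controls and 13.4 ± 17.3 CPM in treated libraries (SD, n = 4, log2 fold change -0.46 ± 0.83 SE, edgeR adjusted p = 0.947). Its treated values were 39.2 CPM in treated 5 and 2.40 to 6.74 CPM in treated 6, 7 and 8, and its log2 fold change was -1.85 without treated 5 and from -0.10 to -0.67 without each other library. alas2, the first enzyme of heme synthesis in red cells, stood at 414.9 ± 149.1 and 332.1 ± 152.3 CPM (-0.32 ± 0.40), and SLC4A1, the red cell anion exchanger, at 741.7 ± 274 and 615.6 ± 260.8 CPM (-0.27 ± 0.39). The second row named SLC4A1 held too few counts to be tested. EPOR, the erythropoietin receptor, had a log2 fold change of -0.44 ± 0.37. Without single libraries alas2 ran from -0.65 (without treated 5) to -0.10 (without control 3), SLC4A1 from -0.55 to -0.05 (the same libraries) and EPOR from -0.63 (without control 4) to -0.16 (without control 3). klf1 and the embryonic globin hbae1.1 had values of -0.03 ± 0.40 and -0.08 ± 0.53. The sign turned for klf1 without control 1, control 3, treated 7 or treated 8 (0.19, 0.01, 0.15 and 0.21) and for hbae1.1 without control 1, control 3, treated 6 or treated 8 (0.18, 0.10, 0.12 and 0.09). The edgeR adjusted p of these 5 genes lay between 0.856 and 0.990. 4 of 11 entries of the embryonic globin list, hbbe1.1 among them, matched no row. The list held 0.36% of counts in controls, where all rows named as globins held 1.02%. A row named HBE1, at 0.276% of all counts, lies outside the list, which so covers only part of the globin transcripts.

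As lists, 22 of 29 erythroid regulators had lower values in treated libraries and 7 higher, with a median log2 fold change of -0.17. The list passed camera (adjusted p = 0.00793, lower) and not with an estimated correlation (adjusted p = 0.376 with an estimated correlation). 0 members passed over all genes and 0 adjusted over the list alone. The members with the smallest p were LDB1 at 135.2 ± 9.19 and 108 ± 11.9 CPM, foxo3b at 117.6 ± 4.63 and 96.0 ± 11.8 CPM, BCL2L1 at 54.4 ± 3.07 and 42.6 ± 5.27 CPM and foxo3a at 57.1 ± 4.41 and 45.6 ± 8.79 CPM. The foxo3a log2 fold change of -0.32 was -0.20 without treated 8. LDB1, foxo3b, BCL2L1 and foxo3a had higher mean CPM than gata1a and klf1 in both groups. The libraries held transcripts of many tissues, so the lower values of these members cannot be assigned to red cells. The second row named LDB1 had -0.20 ± 0.13 (SE). Beside gata1a and klf1, the members GFI1B, TAL1 and klf17 had -0.27 ± 0.50, -0.21 ± 0.35 and -0.15 ± 0.64 (SE), with edgeR adjusted p of 0.944 to 0.978. GFI1B, TAL1 and klf17 were named outside the rule for named genes. Without control 1 the list lost its camera call (adjusted p = 0.124, median -0.03), and the median was -0.10 without control 3, -0.27 without control 4 and -0.27 without treated 5. The other 5 red cell lists did not pass. Red cell maturation and autophagy had a median of -0.18 (camera adjusted p = 0.0531), red cell structure and enzymes -0.12 (0.065), embryonic globins -0.24 (0.0754), heme synthesis -0.17 (0.215) and iron handling -0.13 (0.235). Without control 3 the medians of heme synthesis, red cell structure and iron handling were 0.01, 0.009 and 0.027, that of embryonic globins was -0.03, and without treated 8 that of red cell structure was 0.011. Without treated 5 the medians of embryonic globins, heme synthesis, red cell structure and iron handling were -0.58, -0.48, -0.32 and -0.26, and that of red cell maturation was -0.08 without control 1, -0.29 without control 4 and -0.09 without treated 7. Over the 107 genes of the 6 lists the median was -0.16, with 82 genes lower and 25 higher. The mean score of the 6 lists differed by -0.18 between treated and control libraries (95% interval -0.70 to 0.34, exact permutation p = 0.371).

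Hematopoietic stem and progenitor genes gave no call in camera. RUNX1, needed for the emergence of hematopoietic stem cells, stood at 6.95 ± 1.51 and 6.51 ± 3.49 CPM (edgeR adjusted p = 0.979), with a log2 fold change whose sign turned without control 4, treated 5 or treated 6 (0.02, 0.058 and 0.054), and MYB at 16.5 ± 2.18 and 14.1 ± 4.19 CPM (edgeR adjusted p = 0.907), with a log2 fold change of -0.21 that was -0.04 without treated 5 and -0.35 without treated 8. The list of 22 stem and progenitor genes had a median log2 fold change of 0.10, with 12 members higher and 10 lower (camera adjusted p = 0.128), and the median was 0.18 without control 2 and 0.005 without treated 7. Fry's mixed test, which asks for change in either direction, gave an adjusted p of 0.0418 for it. At an unadjusted edgeR p of at most 0.05, 5 members were higher and 0 lower. The list's share of counts was 0.201% ± 0.00788 in controls and 0.233% ± 0.0227 in treated libraries (SD, n = 4), without overlap between groups, and was not tested. The score, which weighs members equally, had an exact permutation p of 0.4. The genes fli1 and tal1 are also in the endothelial list. RUNX1 and MYB, at the CPM given above, make up only a small part of the list's share. The list also holds Notch pathway genes and chemokine receptors, and the libraries held many tissues. The share can therefore not be assigned to stem cells. SPI1, a myeloid master regulator, stood at 5.94 ± 0.773 and 8.86 ± 1.54 CPM (edgeR adjusted p = 0.756). The myeloid list had a median of -0.13 with 8 members higher and 9 lower (camera adjusted p = 0.127), and the thrombocyte list -0.15 with 1 higher and 8 lower (camera adjusted p = 0.101). The myeloid median was -0.007 without control 1, -0.07 without treated 6 and -0.007 without treated 7, and the thrombocyte median -0.33 without control 1, -0.35 without control 2 and -0.25 without treated 8. With a filter of 5 CPM the stem and progenitor, myeloid and thrombocyte medians were 0.032, -0.054 and -0.05. 0 members of the stem and progenitor, myeloid and thrombocyte lists passed over all genes or adjusted over the list alone, and the same held for the 5 red cell lists that did not pass camera.

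Of 32 lists tested, 14 passed camera at its preset correlation of 0.01, 7 higher and 7 lower in treated libraries. With an estimated correlation 0 passed, and fry's directional test passed 0. Fry's mixed test passed 6: endothelial, p53 and apoptosis, hematopoietic stem and progenitor, pigment cells, cholesterol synthesis and neural genes. Without control 1 camera called 9 lists.

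Endothelial genes lay higher in treated libraries for 18 of 24 members, with a median log2 fold change of 0.48 (camera adjusted p = 2.5e-06, adjusted p = 0.227 with an estimated correlation). 0 members passed over all genes and 2 adjusted over the list alone. Beside stab2, the scavenger receptor stab1 stood at 13.6 ± 5.16 and 26.1 ± 5.44 CPM, and the vascular growth factor receptors FLT4 and flt1 at 4.76 ± 3.40 and 11.3 ± 3.62 CPM and at 2.91 ± 0.972 and 6.84 ± 2.21 CPM. Camera called the list without each library in turn.

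Muscle genes lay higher for 31 of 32 members, with a median log2 fold change of 0.85 (camera adjusted p = 4.66e-18, adjusted p = 0.376 with an estimated correlation). 0 members passed over all genes and 0 adjusted over the list alone. The fast troponin TNNI2 stood at 10.4 ± 7.94 and 45.1 ± 24.9 CPM, the fast myosin myhz1.3 at 956.7 ± 660 and 2234 ± 662.8 CPM, ACTA1 at 63.1 ± 41.9 and 143.7 ± 50.5 CPM and MYOD1 at 6.36 ± 2.89 and 10.9 ± 3.25 CPM. 6 rows carry the name TNNI2 and 2 the name ACTA1, so reads may be split between copies. 2 other tested rows named TNNI2 had log2 fold changes of 0.71 ± 0.71 and -0.61 ± 0.99 (SE), the latter the 1 member that was lower, and the other ACTA1 row 0.71 ± 0.67. The muscle score differed by 1.12 between groups (exact permutation p = 0.171) and by 0.55 without control 1. The median of the list was 0.55 without control 1 and 1.37 without control 4.

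Lens genes lay higher for 10 of 10 members, with a median of 1.23 (camera adjusted p = 8.94e-08, adjusted p = 0.376 with an estimated correlation), 0 past the threshold over all genes and 4 adjusted over the list alone. The crystallins CRYBA4, CRYBB1, cryba1b and CRYBA2 had log2 fold changes of 1.32 ± 0.34, 1.49 ± 0.48, 1.26 ± 0.44 and 1.94 ± 0.69 (SE). Without control 2, cryba1b and CRYBA2 rose to 1.90 and 3.23. The median was 1.89 without control 2 and 0.82 without control 3. Pigment cell genes lay higher for 11 of 18 members, with a median of 0.85 (camera adjusted p = 0.000438, adjusted p = 0.376 with an estimated correlation), 0 past the threshold over all genes and 8 adjusted over the list alone. The melanin enzymes TYR and TYRP1 (2 rows) and the melanosome protein pmela had log2 fold changes of 1.06, 0.90, 1.02 and 0.93. Without treated 8 TYR had 0.68 and the median of this list was 0.24. Genes of DNA replication lay higher for 30 of 38 members, with a median of 0.24 (camera adjusted p = 4.81e-07, adjusted p = 0.376 with an estimated correlation), 0 past the threshold over all genes and 5 adjusted over the list alone. MCM6, a subunit of the replicative helicase, stood at 96.6 ± 11 and 138.7 ± 14.5 CPM, and POLD1, UHRF1 and POLA1 had log2 fold changes of 0.59, 0.43 and 0.39. Without control 4 the median was 0.14. Mesenchyme, notochord and cartilage genes lay higher for 27 of 35 members, with a median of 0.20 (camera adjusted p = 0.0228, adjusted p = 0.635 with an estimated correlation) and 0 past either threshold. PDGFRA, FOXC1 and col8a1a had values of 0.46, 0.73 and 0.43, and FN1 went the other way at -0.45, with col8a1a at 0.28 without control 2 and FN1 at -0.30 without treated 6. The call ended without control 3, treated 7 or treated 8 (camera adjusted p = 0.197, 0.233 and 0.207; medians 0.06, 0.14 and 0.08), and the median was 0.13 without treated 6. Heat shock genes lay higher for 16 of 23 members, with a median of 0.06 and a mean of 0.28 (camera adjusted p = 0.0295, adjusted p = 0.715 with an estimated correlation), 0 past the threshold over all genes and 1 adjusted over the list alone. Beside hsp90aa1.1, the small heat shock proteins HSPB1 and HSPB8 and the collagen chaperone SERPINH1 had values of 1.41, 0.67 and 0.55, of which HSPB1 and HSPB8 fell to 0.90 and 0.38 without treated 8. The call ended without control 2, control 4 or treated 8 (camera adjusted p = 0.223, 0.28 and 0.479; medians 0.014, 0.006 and 0.008), and the median was 0.57 without control 1, 0.28 without treated 7 and 0.11 without treated 5.

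**Figure D3:**
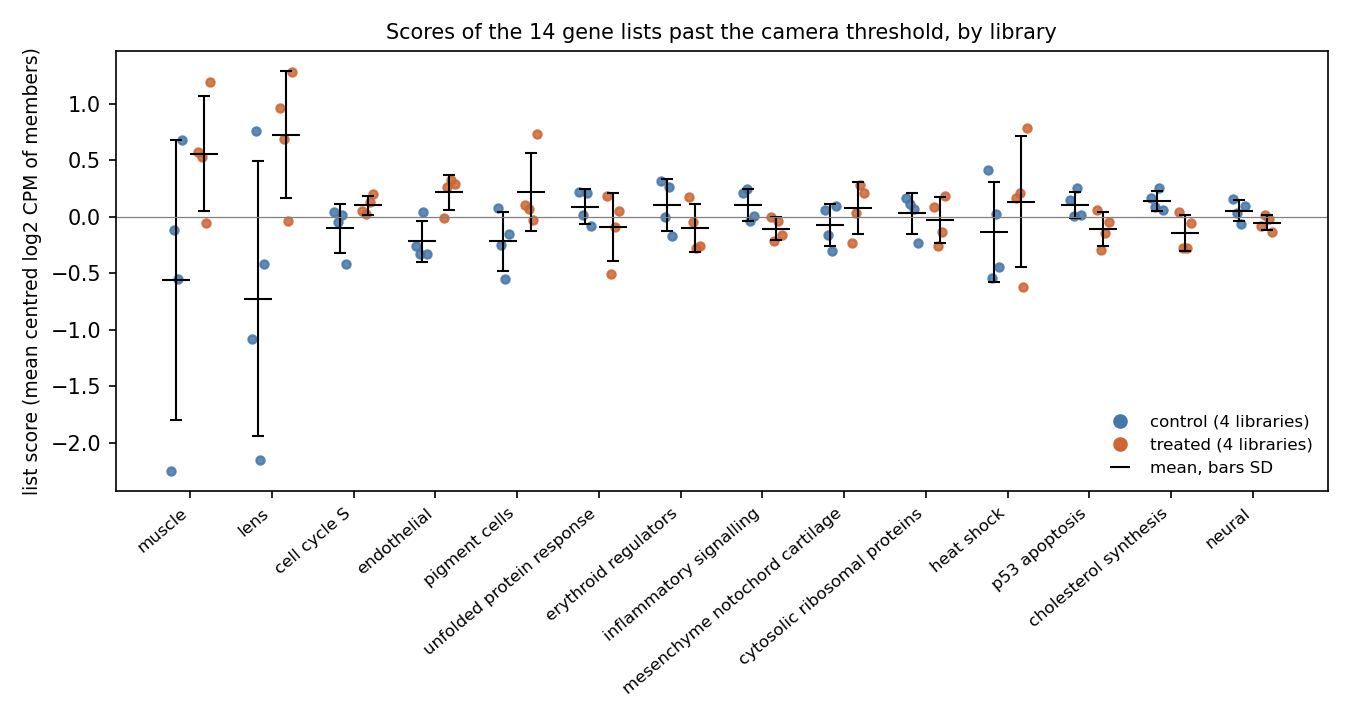
Scores of the 14 lists past the camera threshold (mean of members' log2 CPM, each member centred on its mean over the 8 libraries), with each library as a point, blue for control and orange for treated, and the mean and SD over 4 libraries per group in black. Control 1 had a muscle score of -2.25, against 0.68 in control 4.

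Among lists with lower treated values, inflammatory signalling had 27 of 39 members lower and a median log2 fold change of -0.17 (camera adjusted p = 0.00947, adjusted p = 0.376 with an estimated correlation), with 0 members past either threshold. The chemokine cxcl8a stood at 4.56 ± 1.41 and 1.06 ± 0.909 CPM, the NF-kB inhibitor nfkbiaa at 99.7 ± 25 and 60.5 ± 27.3 CPM, relb at 50.4 ± 7.17 and 36.5 ± 11.9 CPM and the prostaglandin synthase PTGS2 at 43.2 ± 7.44 and 32.7 ± 5.87 CPM. The relb log2 fold change of -0.46 was -0.72 without treated 7. 2 rows carry the name PTGS2, of which 1 is given here. il1b stood at 12.8 ± 9.73 and 12.8 ± 7.06 CPM, with a log2 fold change of -0.007 that turned to between 0.08 and 0.37 without control 1, control 4, treated 5, treated 7 or treated 8, and nfkb1 at 11.9 ± 1.75 and 14.0 ± 2.01 CPM. tnfa held too few counts to be tested. Without treated 6 the camera call of this list ended (adjusted p = 0.0777). The unfolded protein response had 23 of 32 members lower and a median of -0.14 (camera adjusted p = 0.00224, adjusted p = 0.64 with an estimated correlation), with 0 past either threshold. ppp1r15a, CHAC1, CALR and EDEM1 had values of -0.34, -0.42, -0.33 and -0.49, and without treated 6 CALR and EDEM1 had -0.20 and -0.32. Its call ended without control 1 or treated 6 (camera adjusted p = 0.0563 and 0.391), and the median was -0.04 without treated 6, -0.22 without treated 5 and -0.21 without treated 8. p53 and apoptosis genes were lower for 17 of 23 members, with a median of -0.19 (camera adjusted p = 0.0305, adjusted p = 0.376 with an estimated correlation) and 0 past either threshold. TP53INP1 and bbc3 had values of -0.55 and -0.73 and CCNG1 went the other way at 0.28. Without treated 6 bbc3 had -0.46. Their call ended without control 1, control 3 or treated 6 (camera adjusted p = 0.0563, 0.0775 and 0.169), and without rows at 0 in some libraries but abundant in others (adjusted p = 0.0587). Cholesterol synthesis genes were lower for 10 of 18 members, with a median of -0.14 and a mean of -0.27 (camera adjusted p = 0.0396, adjusted p = 0.376 with an estimated correlation), and 0 past either threshold. The receptor ldlra, insig1 and srebf2 had values of -0.95, -0.50 and -0.26. The score of this list had an exact permutation p of 0.0286, the smallest that 4 against 4 libraries can give, and an adjusted p of 0.343 over the 32 lists. Its camera call ended without control 1, control 3, treated 6, treated 7 or treated 8 (adjusted p from 0.0571 to 0.141), and the median was -0.21 without control 1, -0.04 without control 3 and -0.07 without treated 7. The call also ended with a filter of 5 CPM (median -0.011, adjusted p = 0.095) and without rows at 0 in some libraries but abundant in others (median -0.001, adjusted p = 0.112).

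Neural genes were lower for 22 of 33 members, with a median of -0.08 (camera adjusted p = 0.0415, adjusted p = 0.449 with an estimated correlation), 0 past the threshold over all genes and 4 adjusted over the list alone. The synaptic gene SNAP25 and the neurogenic factor NEUROD1 had values of -0.62 and -0.53, while the neural progenitor filament nes went the other way at 0.57. The call ended without control 1, control 2, control 4, treated 5 or treated 8 (camera adjusted p from 0.0556 to 0.225), and the median was -0.05 without control 1, -0.14 without control 3 and -0.05 without treated 5. The call also ended without rows at 0 in some libraries but abundant in others (adjusted p = 0.0512). Cytosolic ribosomal protein genes were lower for 57 of 76 members, with a median of -0.07 (camera adjusted p = 0.0228, adjusted p = 0.784 with an estimated correlation) and 0 past either threshold. RPL27, RPL35A, rps3 and RPS19 had values of -0.23, -0.22, -0.15 and -0.17. Without treated 6 RPL27 and RPL35A had -0.14 and -0.13, without treated 8 RPL27 had -0.34, and without treated 7 RPS19 had -0.11. Its call ended without control 1, control 2, control 3 or treated 7 (camera adjusted p from 0.0775 to 0.657), and its direction turned without treated 6 (median 0.008). The median was -0.02, -0.03, -0.04 and -0.15 without controls 1 to 4 in turn, -0.02 without treated 7 and -0.14 without treated 8.

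The other lists did not pass camera. Their medians were 0.07 for nuclear oxidative phosphorylation genes (adjusted p = 0.195), -0.67 for cardiac genes (0.195), -0.97 for yolk and liver genes (0.308), 0.04 for mitotic genes (0.308), -0.08 for oxidative stress genes (0.392), -0.03 for epidermal genes (0.392), -0.09 for hypoxia and glycolysis genes (0.4), -0.03 for lipid mediator enzymes and receptors (0.825), 0.05 for interferon response genes (0.875) and 0.06 for fatty acid and PPAR genes (0.983), all by limma's camera. For the last 2 lists the median was above 0 while the mean and the camera direction were below it, and for the lipid mediator list the mean was above 0 while the median and the camera direction were below it. With 1 library left out the median crossed 0 for oxidative phosphorylation (-0.064 without treated 8), mitosis (-0.036, -0.045 and -0.011 without control 2, control 4 and treated 8), oxidative stress (0.052 and 0.029 without control 3 and treated 7), epidermis (0.076 without control 2), hypoxia (0.01 without treated 6), fatty acid genes (-0.063 without treated 8), interferon genes (-0.104, -0.061, -0.096 and -0.204 without control 2, control 3, control 4 and treated 6) and lipid mediators (0.018 to 0.141 without each library except treated 8). Camera's direction turned for yolk and liver without control 3 and for cardiac genes without treated 6, with medians of -0.174 and -0.404. 0 members of these lists passed over all genes or adjusted over the list alone.

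In principal components of the 1000 most variable genes, the first component took 22.9% of the variance and set treated 5 (49.98) apart from the other 7 libraries (-12.19 to 0.50). The second took 18.4%, with treated 7 at -36.67 and controls 2 and 3 at 20.66 and 21.19. The 10 most abundant rows took 33.8% ± 1.15 of counts in controls and 33.1% ± 1.67 in treated libraries (SD, n = 4, exact permutation p = 0.571, adjusted p = 0.714), and genes with at least 1 count numbered 18149 ± 618.6 and 17571 ± 760.2 (exact permutation p = 0.286, adjusted p = 0.477). The difference of the former, -0.677 percentage points, was -0.403 without control 2, -0.377 without control 3, -1.20 without control 4, -1.46 without treated 5, -0.435 without treated 6 and -0.169 without treated 8. That of the latter, -578.2, was -325 without control 4, -293.2 without treated 5 and -883.6 without treated 8.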

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

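In 17 results a single library lay far from the other 3 of its group, by the ratio of its gap to the group's range (above 0.829). 242 groups of 4 libraries were tested, of which chance alone gives about 12.1, and each treated library accounts for 3 of the 17, so no library stands out by number.

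Red cell and blood genes were among them. gata1a stood at 39.2 CPM in treated 5 against 2.40 to 6.74 CPM in the other treated libraries, RUNX1 at 11.7 CPM in treated 7 against 4.27 to 5.42, and il1b at 23.3 CPM in treated 6 against 8.09 to 10.6. The endothelial receptor stab1 stood at 21.3 CPM in control 3 against 10.4 to 11.8 in the other controls, and the chemokine cxcl8a at 6.67 CPM in control 2 against 3.77 to 3.92.

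In treated 8 the muscle troponin TNNI2 stood at 82.4 CPM against 31.2 to 34.5 in the other treated libraries, the melanin enzyme TYR at 60.2 CPM against 24.6 to 29.4, and the epidermis score at 0.17 against -0.09 to -0.07. In treated 5, TP53INP1 stood at 42.2 CPM against 25.1 to 25.8 and CHMP1A at 8.11 CPM against 10.0 to 10.2. In treated 6, atf7ip stood at 264 CPM against 330 to 342 and CRYBA2 at 11.1 CPM against 9.59 to 9.81. In treated 7, cacnb4b stood at 61.5 CPM against 42.5 to 45.2, and the score of the mitotic genes at -0.21 against 0.06 to 0.09. Among controls, SERPINH1 stood at 28.1 CPM in control 1 against 14.4 to 16.4, bbc3 at 11.8 CPM in control 2 against 20 to 20.3, and rps3 at 368 CPM in control 4 against 433 to 438.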

How the results depend on the processing

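No paired analysis was possible because the sample numbers 1 to 8 are not shared between the groups. The removals of unnamed rows, of the 10 most abundant rows and of rows at 0 in some libraries but abundant in others, the exact test of list scores and the other settings of the principal components were chosen after seeing the data. Of 22 alternative fits, 15 called 0 genes, as edgeR did. The cause of the other counts was not tested, though DESeq2 adjusted its p-values over fewer genes. DESeq2 called 18 genes (10 at least 2-fold), no low-count filter 4 (2) with 1507 at an unadjusted p of at most 0.05, a filter of 5 CPM in 4 libraries 2 (1), 1 surrogate variable 2 (2), and removal of rows at 0 in some libraries 3 (2). Leaving out single libraries gave 0 to 1 genes (0 to 1 at least 2-fold). The 1 without treated 7 was hsp90aa1.1. The 1 without treated 6 was an unnamed row with 0 counts in treated 5, 7 and 8. That row had 41 counts in treated 6 and 22 to 49 in controls, so its call rests on leaving out treated 6. MRC1 was called in 5 of 23 fits (adjusted p 2.13e-05 to 0.376), stab2 in 4 (0.000101 to 0.421) and atf7ip in 4 (2.73e-05 to 0.399). Scaling to the total count alone moved the median log2 fold change by -0.024. The removal of mitochondrial genes was not run, since no row carries such a name.

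The count of lists past camera, 14, became 0 with an estimated correlation and 0 by fry's directional test. It became 6 by fry's mixed test and 0 by the exact test with adjustment. With a smallest p of 0.0286 over 32 lists, the adjusted exact test could hardly pass any. Unadjusted, the exact permutation p of the 14 lists ran from 0.0286 to 0.743. The lowest was that of cholesterol synthesis, the only 1 at most 0.05, and the highest that of cytosolic ribosomal proteins. The number of lists past camera ran from 9, without control 1, to 19, without treated 5, over left-out libraries. The muscle, lens, endothelial, DNA replication and pigment cell lists passed camera in 15 of 15 settings at the preset correlation, cholesterol synthesis in 8, neural in 9, cytosolic ribosomal proteins in 10, p53 and apoptosis in 11, heat shock and mesenchyme in 12, the unfolded protein response in 13, and erythroid regulators and inflammatory signalling in 14.

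Of 84 named genes, 80 kept their sign in each alternative. Most were named for a small p in these same libraries, which favours a kept sign, so this count does not measure robustness. Those that turned, il1b, RUNX1, hbae1.1 and klf1, were among the genes always named. il1b became 0.004 with upper-quartile scaling, 0.20 in limma-voom, 0.25 with sample weights and 0.067 with 1 surrogate variable, and RUNX1 0.017 with the last. Over left-out libraries il1b ran from -0.48 to 0.37, RUNX1 from -0.53 to 0.058, hbae1.1 from -0.44 to 0.18 and klf1 from -0.48 to 0.21. The fatty acid list turned direction with a median of 0.038 on total counts, 0.058 without unnamed rows, 0.057 without the 10 most abundant rows and 0.06 in fry, the interferon list with 0.16 under the 5 CPM filter and 0.14 without rows at 0 in some libraries, and the lipid mediator list with 0.093 in the latter. Over left-out libraries these 3 medians ran from -0.063 to 0.076, -0.20 to 0.087 and -0.025 to 0.14. The median also crossed 0 there for epidermis (-0.11 to 0.076), mitosis (-0.045 to 0.14), ribosomal proteins (-0.15 to 0.008), hypoxia (-0.14 to 0.01), oxidative phosphorylation (-0.064 to 0.12), heme synthesis (-0.48 to 0.01), red cell structure (-0.32 to 0.011), iron handling (-0.26 to 0.027) and oxidative stress (-0.18 to 0.052). Only camera's direction turned for yolk and liver (-1.34 to -0.17) and cardiac genes (-1.16 to -0.38), whose medians stayed below 0. The share of counts in unnamed rows differed by -0.266 to 0.641 percentage points. At 2502636 to 4794081 counts per library, edgeR called 34% of simulated 2-fold changes.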

Other observations

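The patterns weighed here were noticed in the data. The sign test over lens genes and the test of neighbouring rows were chosen after their results were seen, the choice of which lists count as red cell lists was made after the list scores were seen, and the splits by DESeq2 calls were chosen after its 18 calls were seen.

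Some rows had 0 counts in single libraries and many counts in others of the same group. The genes named in this paragraph were chosen after their values were seen. The hatching gland proteases he1.1 and he1.2 had 0 counts in control 1 and in treated 7, 537 and 136 in treated 8, and 184 and 30 in control 2. The cardiac myosin MYH7 had 242 counts in control 1, 12 in control 3 and 0 in treated 5 and treated 6. NDUFS1, a subunit of respiratory complex I, also had 0 counts in controls 1 and 4 and treated 5 and 7, and 95 to 169 in the other libraries. A 0 in this table therefore need not mean that a gene was not expressed. The muscle genes atp2a1l, myha and myot had 0 counts in control 1 alone, the library of lowest muscle share (0.364%), so some zeros went with few muscle counts. Which zeros reflect tissue was not tested, and they are not read as differences in tissue.

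Splits of the 8 libraries into 4 and 4 were compared with the real one. For edgeR's 0 genes past the threshold, 35 of 35 splits gave as many, with 8 as the highest of the others, but any split reaches a count of 0, so this tests nothing. For the other 3 counts chance could not be excluded. For the 987 genes at an unadjusted p of at most 0.05, 3 of 35 did, with 1027 as the highest. For the 14 lists past camera, 7 of 35 did, with 19 as the highest. For the 18 DESeq2 calls, 6 of 35 did, with 78 as the highest, several times the real count. This points to a structure of the samples. The splits with 78, 67 and 44 calls each kept control 1, control 3 and treated 5 on the same side. Rows named as globins held 1.36%, 1.37% and 1.34% of counts in these libraries and 0.556% to 0.748% in the others. Other splits that kept them together gave 3 and 2 calls, and a split that set control 3 apart gave 40. Whether red cell content caused the high counts was not tested.

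Muscle genes were higher in treated libraries, but without control 1, the lowest library, the difference of mean scores was 0.55 ± 0.44 (SE) in place of 1.12, which is too imprecise to say whether that library alone may account for it. Treated embryos further along in development might show muscle and lens genes together. The deviations of the 2 scores from their group means had a Pearson r of 0.45 (permutation test p = 0.247) and a Spearman rho of 0.74 (permutation test p = 0.0458) over 8 libraries. Pearson r was 0.66 without the 2 farthest. Centring on group means ties the deviations to each other, so these p-values are approximate and may be too small. This explanation stays open. More muscle and nothing else would leave lens genes alone, yet 10 of 10 were higher (exact sign test p = 0.00195), but that test treats genes as independent and the lens score had an exact permutation p of 0.0857 between libraries, so this explanation stays open too. An effect of the lipid on muscle or on the tissue collected was not tested.

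Red cell genes were lower in treated libraries by a score difference of -0.18 ± 0.21 (SE), and chance could not be excluded (exact permutation p = 0.371). Dilution by the larger share of muscle transcripts would lower every other gene by -0.021 on the log2 scale, smaller than the median of -0.16. That median rests on TMM-scaled values, which largely correct for such a shift, while -0.021 comes from shares of all counts. The values are therefore not on the same scale, and the spread over libraries is too wide, so this comparison cannot decide. A candidate explanation is a share of red cells that varied between libraries: scores of embryonic globins, heme synthesis and red cell structure deviated together. The lowest Pearson r of 3 pairs was 0.77 (permutation test p = 0.0285, adjusted p = 0.038, Spearman rho 0.74, permutation test p = 0.0458), which became 0.47 without the 2 farthest libraries. The other pairs had r of 0.86 and 0.93, which became 0.72 and 0.96. Centring on group means ties the deviations to each other. Permuting them freely is therefore only approximate, and these p-values may be too small. This concerns variation between libraries and does not show that treatment lowered the share.

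The rows s100a11 and TRPV6, chosen after their values were seen, had 0 counts in all 4 treated libraries and 77 and 56 counts over the 4 controls. No fold is given, since NDUFS1 had 0 counts in 2 libraries of each group and 95 to 169 in the rest, so a 0 here need not mean that a gene was not expressed. In 4 of 35 splits at least as many rows were at 0 on one side and at 10 or more counts in each library of the other, with 3 rows as the highest of the other splits against 2, so chance could not be excluded. Reads assigned to a neighbouring row might produce such zeros. The largest gain among the 4 rows on each side was 0.87 of the control level, in leng8 beside TRPV6 (3.06 ± 12.8 CPM, SE), and its error leaves this open. A change in expression also stays open.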
